A study of Mus musculus with 6 samples.

How the data were processed

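Sequencing libraries were made from 1 µg of total RNA with a SMARTER mRNA kit, per the labels' protocols, from 3 DMSO and 3 DSF samples of OT-I T cells treated for 2 h. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program, the annotation release and the strandedness are not given in the sources used here.

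The deposited table for the comparison gives an expected count per gene and library. These estimated counts are not normalised, and 12.1 to 12.9% of the values of a library are not whole numbers, as transcript-level estimates are. The same deposited table gives TPM per library and a group mean of TPM, per the file headers, and a length in bases whose kind is not stated. The authors' log2 fold changes with their p-values and adjusted p-values stand beside them, per the file headers, in files titled as DESeq2 output. A further table by the authors holds log2 fold changes and adjusted p-values for DF against DO, DC against DF and DC against DO. The code DC is not explained by the labels, and no library of it was analysed here.

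The column names carry the letters A and B with a number, and no column names a treatment. The deposited mean TPM headed DO equals the mean of the 3 A columns, and the mean headed DF that of the 3 B columns, in all 55536 genes within 0.0001 TPM, while the crossed assignment does so in 28853 genes. DO and DF were read as DMSO and DSF from their letters, and the numbers as replicate numbers. The mapping of libraries to groups rests on that reading, which no label states outright. Of the columns holding values per library, 0 were left unused.

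The design had assumed whole counts, so the estimated counts were rounded to whole numbers and tested as planned. Library totals were 18528236, 21893720 and 20149539 for DMSO and 18082264, 19611354 and 20951998 for DSF. A floor of 3 counts covers counting error only, since the reads carry no molecular identifiers that the labels mention. Genes were filtered with filterByExpr of edgeR, which left 14318 genes and removed 41218. Counts were scaled by TMM, with factors between 0.9952 and 1.0053, and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with the group as the only term. Changes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are approximate, taken as the absolute log2 fold change over the square root of the test's F statistic. CPM are counts-per-million values scaled by TMM.

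The 26 gene lists, the test, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 8 genes with the largest rises and the 8 with the largest falls among called genes with a mean of at least 5 CPM, non-overlapping groups and a symbol that is not a predicted model. It added the 3 members with the smallest p of each list with at least 3 called members, and Lck, Cd69, Nr4a1, Ifng, Tnf, Gzmb, Hmox1, Mt1 and Hspa1b in any case. It gave 78 genes, of which 74 were called, and some of them are not reported here. Other members of a list named in the text were chosen after their values were seen. The lists hold 487 tested genes in all and cover immediate early and T cell receptor response, effector cytokines and cytotoxicity, proximal T cell receptor signalling, naive and memory T cells, inhibitory receptors, NF-kappaB targets, NRF2 targets, metal response, heat shock, integrated stress response, unfolded protein response, proteasome and p97-NPL4, p53 targets, aldehyde dehydrogenases, inflammasome, glycolysis, cholesterol synthesis, oxidative phosphorylation, mitochondrial transcripts, type I interferon response, S and G2/M phase, and markers of B cells, myeloid and dendritic cells, CD4 and regulatory T cells, natural killer cells and stromal, endothelial and erythroid cells. Ccr7, Gzma and Aldh1l2 each stand in 2 lists.

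Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 between genes and again with an estimated correlation, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. Fry was run beside it. Terms of the Gene Ontology, from the authors' annotation in the deposited table, were tested the same way over 1994 terms of 15 to 500 tested genes, with all tested genes as the background.

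Replicate libraries had a chi-square per degree of freedom of 2.16 to 4.03 over genes with at least 20 counts, against counting error only, so no pair agreed within counting error and each was kept as a library of its own. That value cannot show whether libraries came from separate samples. Groups of 3 are too small for a test of outlying libraries. Gene positions came from GENCODE M21, in which all 55536 deposited identifiers and symbols were found.

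The pipeline was tested on simulated data drawn from the means and sizes of these libraries. For the DSF against DMSO comparison with 14318 genes, edgeR recovered 64% of genes changed 1.25-fold, 76% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, of 50 each, with 13 false calls. The changed genes were drawn only from those above 1 CPM on average, so recovery of lower genes was not simulated. With no gene changed it made 0 calls, limma-voom 3 and DESeq2 0. A simulated list of 20 genes raised 1.25-fold gave a camera adjusted p of 3.48e-24, or adjusted p = 0.00869 with an estimated correlation. The simulated genes were drawn independently and no gene outside that list was changed, whereas 22.9% of the real genes were called. Camera can therefore have less power on the real data.

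Alternatives were size factors of the DESeq2 kind, no filter and a stricter filter on low counts, the replicate number as a block, leaving out each library in turn, limma-voom, DESeq2 1.42.0, a test against a fold change of 1.5, an adjusted p under 0.01, an estimated correlation and protein-coding genes alone. Unrounded counts, a smooth trend of gene length and GC content taken out of each library, genes with no overlapping gene, and the counts of genes changed at least 2-fold were added after the data had been seen. The trend was fitted with an intercept, so the mean deviation of each library from the gene means was taken out with it. Pseudocount alternatives planned for tables without counts did not apply.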

Results

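RNA was sequenced from primary OT-I T cells of mouse lymph nodes kept for 2 h with disulfiram (DSF) or with its solvent, dimethyl sulfoxide (DMSO). OT-I mice carry a transgenic T cell receptor for an ovalbumin peptide, and most of their T cells are CD8 T cells. DSF is a thiuram disulfide used against alcohol dependence that inhibits aldehyde dehydrogenases. Its concentration and any stimulation of the cells are not given in the labels used here. In DMSO, Gzmb, Il2rb, Il2ra and Tnfrsf9 averaged 2698, 1452, 795 and 748 CPM, so the cells cannot be taken as resting. Each group held 3 libraries that the labels call biological replicates, without naming separate animals or cultures. The p-values therefore measure the spread between these libraries. The DMSO libraries held 18528236, 21893720 and 20149539 counts and the DSF libraries 18082264, 19611354 and 20951998. Between 21286 and 21779 genes had a count above 0 in a library, and 3 counts, taken as the floor, were worth 0.137 to 0.166 counts-per-million units (CPM). Every direction below rests on reading the deposited group codes DO and DF as DMSO and DSF.

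The comparison asked which transcripts differed after 2 h of DSF. Tppp, which encodes a tubulin polymerization-promoting protein, rose 49.5-fold, from 0.352 ± 0.158 to 17.4 ± 1.26 CPM (mean ± SD, n = 3 per group). Ralgds, which encodes an exchange factor for Ral GTPases, rose 13.2-fold, from 24.8 ± 1.36 to 327 ± 11 CPM. The activation marker Cd69 rose 2.91-fold, and the glucose transporter gene Slc2a3 rose 2.36-fold. Of 19 measured effector genes 14 fell, among them the chemokine gene Ccl4, to 0.401 of its DMSO level, and of 23 measured type I interferon response genes 10 fell, among them Mx1, to 0.609. Both lists shifted down by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.0615 and adjusted p = 0.0933). The estimated correlations were -0.038 and -0.041, below the preset 0.01, so correlation between members does not account for these lost calls. Estimating the correlation leaves camera few degrees of freedom with 6 libraries.

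By edgeR's quasi-likelihood test, 3276 of the 14318 genes tested (22.9%) changed at a Benjamini-Hochberg adjusted p under 0.05, of which 1655 were higher and 1621 lower with DSF. The change was small in most of them, with a median absolute log2 fold change of 0.28. Of the genes that changed at least 2-fold, 214 were higher and 56 lower, and 90 of the 214 lay below 1 CPM in DMSO. The libraries of both groups did not overlap in 5072 genes, 35.4% of those tested, where chance gives 10%. Libraries of 1 group correlated at 0.9917 to 0.9928 across genes in log2 CPM, and libraries of different groups at 0.9842 to 0.9866. The first principal component held 47.2% of the variance, and the biological coefficient of variation was 4.4%.

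**Figure D1:**
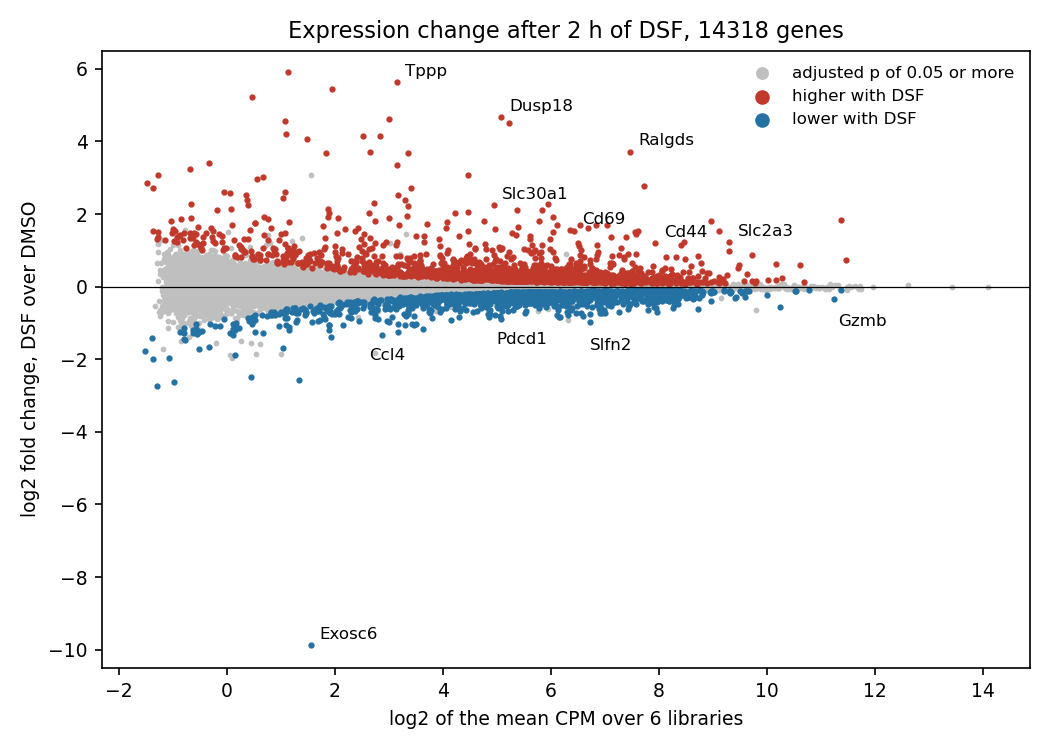
Each point is 1 of 14318 tested genes, with the log2 of its mean CPM over the 6 libraries on the horizontal axis and its log2 fold change, DSF over DMSO, on the vertical axis. Red points are the 1655 genes higher with DSF and blue points the 1621 lower, and Exosc6, at 0 in every DSF library, has a fitted value that depends on the small count added before fitting.

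The genes with the largest rises among those of at least 5 CPM on average included Tppp, Dusp18, Tub, Tppp3, Lrrc23, Ralgds and Spns2. Their log2 fold changes ran from 3.70 ± 0.18 (SE) for Spns2, which encodes a sphingosine-1-phosphate transporter, to 5.63 ± 0.19 for Tppp. Dusp18, a dual-specificity phosphatase gene, rose 25.3-fold from 2.55 ± 0.297 to 65.3 ± 3.15 CPM. Tub rose 24.5-fold from 0.609 ± 0.293 to 15.5 ± 1.58 CPM, Tppp3 17.9-fold from 0.751 ± 0.2 to 13.6 ± 0.878 CPM, and Lrrc23 17.8-fold from 0.599 ± 0.231 to 10.9 ± 1.68 CPM. Ralgds (ENSMUSG00000026821) lies on chromosome 2 at 28513125 to 28553081 of GRCm38 and shares no exon sequence with another annotated gene. Exons of Tub overlap Ric3 and Gm26599 and exons of Spns2 overlap Mybbp1a, in each case on the opposite strand, and whether counting used the strand is not given in the sources used here. Among the genes named below, exons of Dusp5, Klf3, Cd160, Slc30a1, Sqstm1, Mt2, Hspd1, Cebpg, Syvn1, Psma4, Cdc20, Zbtb7b, Cxcr5, Ikzf2 and Cxcl10 overlap a gene on the opposite strand, and those of Lck, Ifng, Cebpg and Cd74 one on the same strand, so their counts are uncertain to that extent.

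The 8 largest falls by the same rule were Ccl4, Tnfsf11, Ccr4, Ccr2, Ifit1bl1, Fam20a, Arl4d and Slfn2, with log2 fold changes between -1.32 ± 0.13 and -0.98 ± 0.05 (SE). Tnfsf11, the gene for the cytokine RANKL, fell from 12.8 ± 0.464 to 5.34 ± 0.165 CPM. The chemokine receptor genes Ccr4 and Ccr2 fell to 0.443 and 0.483 of their DMSO levels, to 7.59 ± 0.134 and 6.39 ± 0.182 CPM. Slfn2, a schlafen gene on chromosome 11 at 83065112 to 83070678, was the most abundant of the 8 and fell from 140.2 ± 3.96 to 70.8 ± 3.5 CPM. Ifit1bl1 has close relatives in the genome among which the authors' counting could split reads, so its fall to 0.485 is uncertain.

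**Figure D2:**
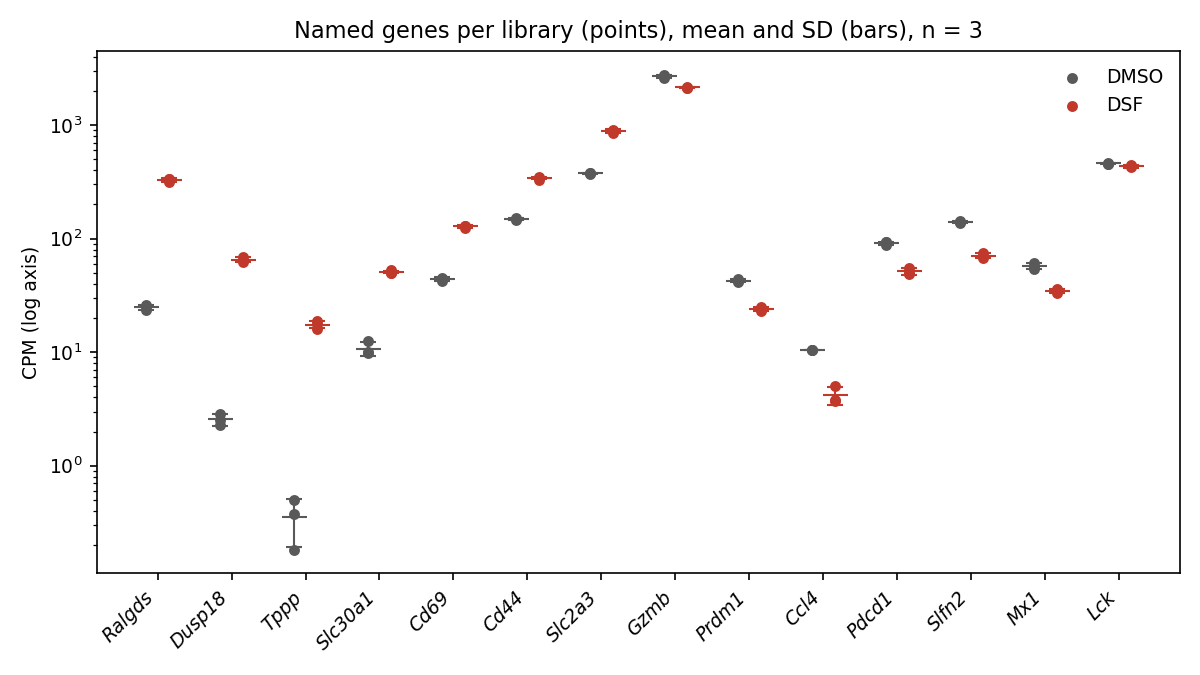
Points are the CPM of 14 named genes in each library on a log axis, grey for DMSO and red for DSF, with bars for the mean and SD of 3 libraries. Ralgds sits near 327 CPM in all DSF libraries and near 24.8 CPM in DMSO, while Lck sits at 459 and 434 CPM.

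Most of the measured effector genes fell. Of 19 measured genes for effector cytokines and cytotoxicity, 14 were lower with DSF, 0 were higher and 5 did not pass, and 16 were lower and 0 higher adjusted over the list alone. The median log2 fold change was -0.45, and camera's adjusted p was 7.18e-09 with the preset correlation, but adjusted p = 0.0615 with an estimated correlation. Prdm1, which encodes the transcription factor BLIMP-1, fell from 42.5 ± 1.38 to 24.0 ± 1.02 CPM, and Id2 fell from 98.7 ± 2.57 to 65.5 ± 0.754 CPM. Gzmb, the gene for granzyme B, fell from 2698 ± 88.2 to 2142 ± 26.5 CPM, and Tnf fell from 14.9 ± 0.366 to 10.9 ± 0.375 CPM. Ifng, at 69.4 ± 1.86 and 63.4 ± 4.21 CPM, did not pass edgeR's test (adjusted p = 0.067, or 0.0185 without DSF library 1), nor did the perforin gene Prf1, at 204 ± 5.13 and 206 ± 5.53 CPM. Il2 had at most 2 counts in any library and was not tested.

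Some genes of the type I interferon response also fell. Of 23 measured, 10 were lower, 0 higher and 13 did not pass, with 11 lower and 0 higher adjusted over the list alone. The median log2 fold change was -0.31, and camera's adjusted p was 6.04e-05, or adjusted p = 0.0933 with an estimated correlation. Mx1 fell from 57.2 ± 3.56 to 34.8 ± 1.51 CPM and Ifit2 fell from 25.2 ± 0.381 to 14.2 ± 1.15 CPM. Stat2, at 75.5 ± 1.62 and 75.5 ± 0.865 CPM, and Cxcl10, at 2.44 ± 0.289 and 2.45 ± 0.319 CPM, did not pass.

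In the same libraries, some markers of other cell types passed. Of 14 myeloid and dendritic cell markers, 3 were lower and 0 higher, with the same counts adjusted over the list alone, and camera's adjusted p was 0.675. They were Xcr1, from 10.7 ± 1.59 to 5.38 ± 1.1 CPM, Clec10a, from 0.842 ± 0.296 to 0.313 ± 0.209 CPM, and Mpeg1, from 15.5 ± 0.981 to 13.1 ± 1.02 CPM. By edgeR's test the call of Clec10a ended without DMSO library 2 or DSF library 1 or 3 (adjusted p = 0.182, 0.0611 and 0.17), and that of Mpeg1 without DMSO library 1 or 3 or DSF library 1 or 3 (adjusted p = 0.0826, 0.177, 0.0603 and 0.246). Lyz2, at 11.5 ± 1.09 and 11 ± 1.11 CPM, did not pass. Of 15 B cell markers, Ighm, from 192 ± 2.75 to 175 ± 5.76 CPM, and Igkc were lower, 1 of them adjusted over the list alone, and Cd74 stood at 32.8 ± 3.87 and 34.0 ± 2.6 CPM. That list's median of 0.05, mean of -0.04 and downward test (camera's adjusted p = 0.949) differed in sign. Among 6 CD4 and regulatory T cell markers Zbtb7b and Cxcr5 were higher and Ikzf2 lower, with the same counts adjusted over the list alone and camera's adjusted p of 0.864. The call of Ikzf2 ended without DSF library 1 (edgeR's adjusted p = 0.0824). Of 4 natural killer cell markers, Gzma, which the effector list also holds, was lower over all genes and adjusted over the list alone (camera's adjusted p = 0.675). None of 6 stromal, endothelial and erythroid markers passed over all genes or adjusted over the list alone (camera's adjusted p = 0.864).

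Genes of proximal T cell receptor signalling shifted down slightly. Of 28 measured, 12 were lower and 4 higher, with 15 and 4 adjusted over the list alone, at a median log2 fold change of -0.09. Camera's adjusted p was 0.00357, or adjusted p = 0.272 with an estimated correlation. The kinase gene Prkcq fell from 153 ± 3.97 to 118 ± 2.22 CPM and Vav1 fell from 117 ± 4.45 to 92.8 ± 1.31 CPM, whereas the costimulatory receptor gene Cd28 rose from 425 ± 6.43 to 497 ± 18.1 CPM. Cd8a fell from 411 ± 5.05 to 350 ± 5.64 CPM. Lck, the kinase that starts receptor signalling, was at 459 ± 5.45 and 434 ± 11.4 CPM and did not pass edgeR's test (adjusted p = 0.0685). It passed with a trend of gene length and GC content taken out of each library, an alternative added after the data were seen (edgeR's adjusted p = 0.000845). That step also recentred each library, and the log2 fold change of Lck went from -0.08 to -0.11.

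Immediate early and T cell receptor response genes went both ways. Of 30 measured, 6 were higher and 13 lower, with 7 and 16 adjusted over the list alone, and the list as a whole did not pass (camera's adjusted p = 0.137). Cd69 rose from 43.9 ± 1.56 to 128 ± 3.12 CPM and Fosb from 20.3 ± 1.62 to 63.9 ± 5.46 CPM. Dusp5, the gene for a phosphatase of ERK, fell from 189.5 ± 4.64 to 117 ± 6.54 CPM, and Myc fell from 110.5 ± 5.16 to 66.8 ± 3.81 CPM. Nr4a1 was at 59.1 ± 2.14 and 52.3 ± 2.64 CPM, lower by edgeR's test (adjusted p = 0.0125), a call that ended without DMSO library 2 or 3 or without DSF library 1 or 3 (adjusted p = 0.0573, 0.0578, 0.105 and 0.0513).

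Naive and memory T cell genes and inhibitory receptor genes were likewise split. Of 18 naive and memory genes, 6 were higher and 8 lower, with 6 and 10 adjusted over the list alone (camera's adjusted p = 0.517), and the list's median of -0.18 and its downward test differed in sign from its mean of 0.07. The adhesion receptor gene Cd44 rose from 149 ± 3.61 to 342 ± 9.95 CPM, Klf3 from 11.3 ± 0.531 to 33.1 ± 0.762 CPM, and Ccr7, which encodes a lymph node homing receptor, from 309 ± 7.38 to 459 ± 15.5 CPM. Il2rb, a receptor chain for interleukins 2 and 15, fell from 1452 ± 62.7 to 983 ± 46.2 CPM. Of 12 inhibitory receptor and exhaustion genes, 2 were higher and 4 lower, with 2 and 5 adjusted over the list alone (camera's adjusted p = 0.197). Pdcd1, the gene for PD-1, fell from 91.2 ± 2.64 to 51.4 ± 3.59 CPM and Cd160 from 26.2 ± 1.17 to 16.9 ± 1.44 CPM, and Vsir, the gene for VISTA, rose from 83.1 ± 3.27 to 128 ± 0.385 CPM. Of 21 NF-kappaB targets, 6 were higher and 5 lower, with 7 and 5 adjusted over the list alone (camera's adjusted p = 0.941), at a median and mean of -0.01 and an upward test. Among them Tnfaip3 rose 1.37-fold and Nfkbid fell to 0.645 of its DMSO level.

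None of the lists for metal, oxidant, heat shock, integrated stress, unfolded protein and p53 responses passed camera, with 1, the oxidant list, at an unadjusted p under 0.05. Fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, called the metal, oxidant, integrated stress and unfolded protein lists (adjusted p = 0.00092, 0.004, 0.00545 and 0.0343). Their mean log2 fold changes were 0.15, 0.06, 0.09 and -0.03, so the unfolded protein list leaned down and the others up. In the metal response and copper handling list, 3 of 17 genes were higher and 1 lower, with the same counts adjusted over the list alone (camera's adjusted p = 0.254). Slc30a1, which encodes a zinc exporter, rose 4.76-fold from 10.7 ± 1.49 to 50.8 ± 1.45 CPM, and the metallothionein gene Mt1 rose from 156 ± 9.51 to 206 ± 6.12 CPM and Mt2 from 157 ± 8.37 to 202 ± 4.34 CPM. Of 23 NRF2 antioxidant targets, 6 were higher and 3 lower, with 7 and 3 adjusted over the list alone (camera's adjusted p = 0.138). Sqstm1 rose 1.3-fold and Txn1 1.12-fold, Osgin1 fell to 0.554, and Hmox1, at 15.9 ± 1.66 and 17.9 ± 1.33 CPM, did not pass.

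Of 24 heat shock genes, 6 were higher and 3 lower, with the same counts adjusted over the list alone (camera's adjusted p = 0.77). Hsf2, a heat shock transcription factor gene, rose 2.05-fold from 21.9 ± 0.884 to 44.9 ± 2.53 CPM, and Hspd1 fell to 0.841. Hspa1b, which shares most of its sequence with Hspa1a, was at 16.5 ± 2.15 and 16.8 ± 1.99 CPM and did not pass. Of 23 integrated stress response genes, 8 were higher and 3 lower, with 9 and 3 adjusted over the list alone (camera's adjusted p = 0.197). Atf3 rose 2.63-fold from 27.1 ± 1.62 to 71.3 ± 4.57 CPM and Cebpg 1.24-fold, and Ddit4 fell to 0.78. Of 23 unfolded protein response genes, Herpud1 and Syvn1 were higher and 4, including Hyou1 and Dnajc3, were lower, with 2 and 6 adjusted over the list alone (camera's adjusted p = 0.275). Of 19 p53 targets, 3 were higher, including Sesn1 and Fas, and 3 lower, including Aen, with the same counts adjusted over the list alone (camera's adjusted p = 0.517).

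Of 30 genes of the proteasome and the p97-NPL4 segregase, whose subunit NPL4 binds a copper complex of a disulfiram metabolite, 4 were lower and 0 higher, with 3 and 0 adjusted over the list alone. Psmc5, Psma4 and Psmc1 fell to 0.889, 0.913 and 0.907 of their DMSO levels. By edgeR's test the call of Psma4 ended without DSF library 1 or 3 (adjusted p = 0.0883 and 0.055), and that of Psmc1 without DMSO library 1 or DSF library 2 or 3 (adjusted p = 0.114, 0.0795 and 0.0581). The list shifted down by a median log2 fold change of -0.06 (camera's adjusted p = 0.00709, or adjusted p = 0.272 with an estimated correlation). None of 13 aldehyde dehydrogenase genes passed over all genes or adjusted over the list alone (camera's adjusted p = 0.675, with a median of 0.02). Of 12 inflammasome and pyroptosis genes, Casp4 was higher and Aim2 lower, with the same counts adjusted over the list alone (camera's adjusted p = 0.311).

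Glycolysis genes shifted up. Of 20 measured, 6 were higher and 1 lower, with 6 and 2 adjusted over the list alone, at a median log2 fold change of 0.05. Camera's adjusted p was 0.0219, or adjusted p = 0.349 with an estimated correlation, and the call ended without DMSO library 3 (adjusted p = 0.0605) or DSF library 3 (adjusted p = 0.0551). The genes that rose furthest encode membrane transporters rather than enzymes. They were Slc2a3, from 375 ± 4.4 to 884 ± 31.6 CPM, and the monocarboxylate transporter gene Slc16a1, from 109 ± 1.25 to 199 ± 7.56 CPM, whereas the hexokinase gene Hk2 fell from 43.6 ± 2.33 to 32.7 ± 1.51 CPM. Of 22 cholesterol synthesis genes, 6 were lower and 0 higher, with the same counts adjusted over the list alone, among them Stard4 and Insig1 (camera's adjusted p = 0.173). Of 27 nuclear genes of oxidative phosphorylation, Ndufa4 was lower, and 0 passed adjusted over the list alone (camera's adjusted p = 0.0609, or 0.0415 without DMSO library 3). None of 13 mitochondrially encoded transcripts passed over all genes or adjusted over the list alone (camera's adjusted p = 0.279), and they made up 2.07 to 2.3% of the counts of each library.

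Genes of S and G2/M phase shifted down. Of 28 measured, 15 were lower and 1, Cdc6, was higher, with 16 and 2 adjusted over the list alone, at a median log2 fold change of -0.12 (camera's adjusted p = 0.0016, or adjusted p = 0.117 with an estimated correlation). The cyclin E1 gene Ccne1 fell from 41.1 ± 0.258 to 28.6 ± 2.8 CPM, the kinesin gene Cenpe fell from 188 ± 3.08 to 158 ± 3.86 CPM and Cdc20 fell from 155 ± 2.99 to 129 ± 3.42 CPM. The proliferation marker Mki67, at 1022 ± 29.7 and 974 ± 14.5 CPM, did not pass.

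**Figure D3:**
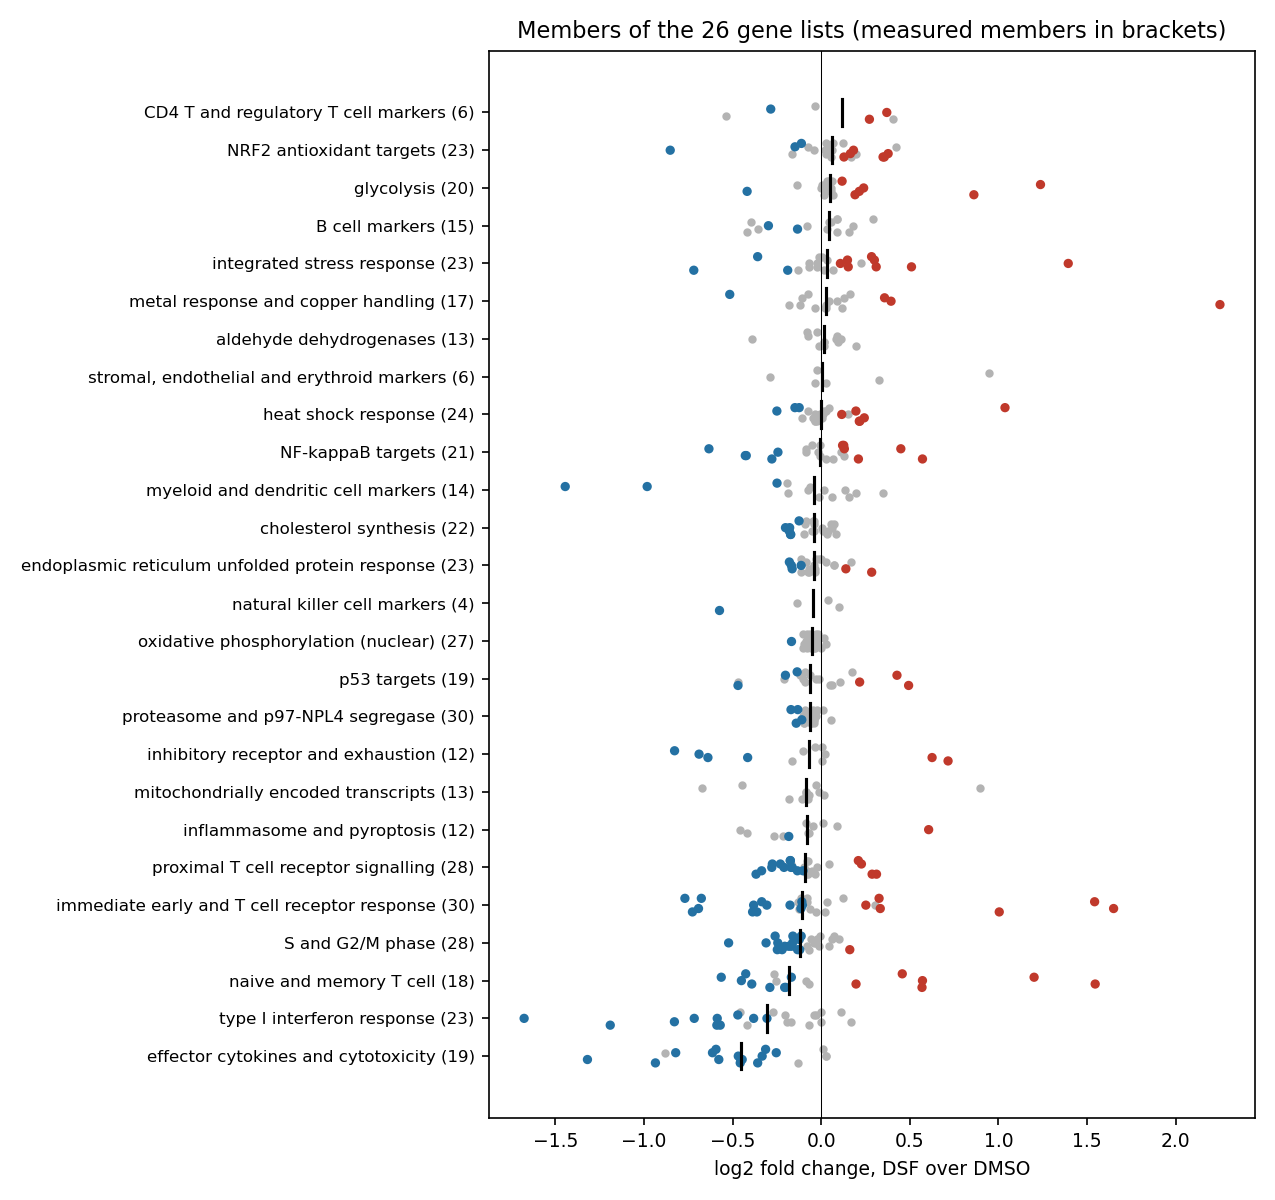
Points are the log2 fold changes, DSF over DMSO, of the measured members of 26 gene lists, red or blue where the gene passed higher or lower and grey where it did not, and black bars are medians. The effector list has the lowest median, -0.45, and the type I interferon list follows at -0.31.

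Of the 26 lists, 6 shifted by camera with the preset correlation, 1 up and 5 down. With an estimated correlation 0 did, against 3 at an unadjusted p under 0.05, while fry called 14. In the authors' deposited table, 189 genes were called between DF and DO, 164 higher and 25 lower with DF, each with an absolute log2 fold change of at least 1. Of these, 187 were also called here, all 187 in the same direction. Against a fold change of 1.5 rather than any change, edgeR called 218 genes. With a trend of gene length and GC content taken out of each library, 1467 genes were higher and 2347 lower, a higher share of 38.5% against 50.5%. That step also recentred each library, and the median log2 fold change of all genes moved from -0.003 to -0.023. The swing to lower genes therefore cannot be put down to length and GC content alone. The number of genes at least 2-fold lower ranged from 15 to 96 over the alternatives tried.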

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

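The overlap tests in this part were chosen only after the calls in the deposited tables had been seen.

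The authors' deposited table holds signal outside the DSF and DMSO comparison, in contrasts with a group coded DC that the labels do not explain. It calls 165 genes between DC and DF, 8 higher and 157 lower in DC, and 1 gene between DC and DO, Slc30a1, higher in DC by a log2 fold change of 1.89. At an adjusted p under 0.05 with no limit on the fold change, that table holds 1913 genes for DC against DF and 93 for DC against DO. Of the 164 genes it calls higher in DF than in DO, 139 are among the 157 it calls lower in DC than in DF. Independent lists among the 25802 genes tested in both would share 1. Both contrasts use the same DF libraries, and 20 simulated draws of unchanged groups against such shared libraries gave a median overlap of 0 and at most 1. The libraries of DC were not analysed here and 3 DF libraries cannot be split into groups of at least 2, so part of the excess can come from the shared libraries. The contrasts are also tied by arithmetic, since DC differed from DO in only 1 called gene. Genes higher in DF than in DO must then mostly be lower in DC than in DF. The overlap thus restates that DC lay close to DO and is no separate result. The simulated value leaves out real effects, and the independent one leaves out the shared libraries. No biological explanation of the overlap was tested.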

How the results depend on the processing

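The length and GC correction, unrounded counts, the restriction to genes with no overlapping gene and the counts of genes changed at least 2-fold were tests chosen only after the data had been seen. Of 1012 values of the 78 named genes over 13 alternatives, 986 kept their direction and side of the threshold, 19 lost the call, 4 gained it, and 3 changed sign, none of a called gene. Of 338 values of lists, the counts were 317, 8, 1 and 12. DESeq2 gave no adjusted p for Clec10a.

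Against the 3276 genes changed, glmTreat at a 1.5-fold threshold called 218 by its stricter question, and the 8852 genes with no overlapping gene gave 2083, fewer genes being tested. DESeq2 gave 2555, limma-voom 3104, DESeq2-type size factors 3265, no filter 3229, the stricter filter 3256, an adjusted p under 0.01 2224 and the length and GC correction 3814. The 56 genes at least 2-fold lower became 96 with no filter, 33 with the stricter filter, 28 with DESeq2, 15 with glmTreat and 30 at an adjusted p under 0.01. The filters change by construction which low genes are tested, and stricter thresholds call fewer. For DESeq2 the cause was not tested. The 6 lists shifted became 0 with an estimated correlation.

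Leaving out 1 library gave 2565 (without DSF library 3) to 2972 (without DMSO library 1) changed genes, 198 to 219 at least 2-fold higher, 44 to 59 at least 2-fold lower and 5 to 6 lists. Calls of Psmc1, Psma4, Mpeg1, Clec10a, Ikzf2 and Nr4a1 ended without 1 or more libraries, with adjusted p up to 0.114, 0.0883, 0.246, 0.182, 0.0824 and 0.105. Mpeg1 also lost its call with limma-voom (0.0553) and DESeq2 (0.143). Clec10a had log2 fold changes from -2.0 without DSF library 2 to -0.99 without DSF library 3. Ifng passed without DSF library 1 (adjusted p = 0.0185), and oxidative phosphorylation without DMSO library 3 (adjusted p = 0.0415).

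Directions that turned were all of results that had not passed. Hspa1b had a log2 fold change of -0.03 with the length and GC correction and -0.06 to 0.13 without 1 library. The test of the stromal list turned with no filter (adjusted p = 0.797), and that of the B cell list with the replicate block (0.85) and in protein-coding genes (0.501). Without 1 library, adjusted p ran from 0.632 to 0.978 for B cell, 0.874 to 0.981 for NF-kappaB and 0.359 to 0.899 for stromal genes, each turning in some. The cause was not tested.

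With the replicate number as a block, edgeR called 3829 genes, 3259 of them shared with the 3276 in the same direction, and Lck (adjusted p = 0.0162, or 0.000845 with the length and GC correction) and Ifng (adjusted p = 0.0299) passed. Of the 78 named genes and the 26 lists, none lost its call with the block. Deviations of same-numbered libraries correlated at 0.035 to 0.055 and others at -0.052 to 0.004. Each of the 6 libraries correlated best with its own number, a hint from the data and not the design. On the second principal component, with 14.9% of the variance, DMSO library 1 and DSF library 1 lay at 18.9 and 15.16. The other libraries lay between -12.08 and -5.68 on it. Depth limits genes near the floor of 0.137 to 0.166 CPM.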

Other observations

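The tests of Gene Ontology terms, of the most abundant genes, of T cell lineage genes and of B cell, myeloid and dendritic cell markers were chosen only after the results they bear on had been seen.

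Genes for making ribosomes were lower with DSF. Of 102 genes annotated to ribosome biogenesis, 58 were lower and 1 higher by edgeR's test (camera's adjusted p = 5.33e-10, or adjusted p = 0.635 with an estimated correlation). Gnl3, which encodes nucleostemin, fell from 100.2 ± 6.28 to 64.7 ± 1.69 CPM (mean ± SD, n = 3 per group), Tsr1 fell from 156 ± 9.21 to 109 ± 3.69 CPM, and Nop56 fell to 0.767 of its DMSO level. Of 41 genes of the small-subunit processome, 26 were lower and 0 higher (camera's adjusted p = 2.53e-06, or adjusted p = 0.635 with an estimated correlation). Genes annotated to the cellular response to interferon-beta also fell, 26 of 45 against 3 higher, among them the immunity-related GTPase genes Igtp, to 0.659, and Iigp1, to 0.594, and Tgtp1, to 0.617, a value left uncertain by its near-identical neighbour (camera's adjusted p = 2.12e-08, or adjusted p = 0.635 with an estimated correlation). Exons of Gnl3, Nop56, Igtp and Tgtp1 overlap a gene on the same strand and those of Gnl3, Nop56 and Tsr1 one on the opposite strand, so their counts are uncertain to that extent. In all, 47 of 1994 terms shifted up and 50 down with the preset correlation, and 0 with an estimated one. The estimated test has little power with 6 libraries. A simulated list of independent genes went from a camera adjusted p of 3.48e-24 to 0.00869 with it, over only 26 lists. The 0 over 1994 terms, and the adjusted p of 0.635, therefore cannot decide whether correlation between genes accounts for these shifts.

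Some genes of cilia rose. Of 129 genes annotated to cilium assembly, 46 were higher and 5 lower (camera's adjusted p = 2.53e-06, or adjusted p = 0.635 with an estimated correlation). They include transcription factor genes of the RFX family that act in ciliated cells, Rfx3, which rose 4.34-fold from 15.5 ± 0.255 to 67.5 ± 4.07 CPM, and Rfx2, which rose 10.2-fold from 1.57 ± 0.284 to 16.2 ± 1.11 CPM. Arl13b, which encodes a GTPase of the ciliary membrane, rose 3.53-fold, and Ttbk2, whose exons overlap Cdan1 on the same strand, 3.51-fold. Exosc6, a subunit gene of the RNA exosome named after its values were seen, had 5.91 ± 0.81 CPM in DMSO and 0 counts in every DSF library, at least 39.1-fold lower against a floor of 3 counts at the mean library size (0.151 CPM). Its exon sequence overlaps that of Aars on the same strand (chromosome 8, 111056339 to 111057664 of GRCm38), and how the authors' program assigned reads between them is not given in the sources used here.

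Genes changed at least 2-fold were mostly higher, 214 against 56. A trend of gene length and GC content may shape fold changes, but with it taken out 93.5% of the 214 stayed at least 2-fold higher. Reads of overlapping genes are unlikely as the whole cause, since 33.6% of the 214 overlap another gene (95% interval 27.3 to 40.4%), against 38.2% of all tested genes, and the share of counts in the 10 most abundant genes differed between groups by 0.03 percentage points. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one with 3276 against 0 in the highest other. These 10 splits are too few for a share under 0.05. Every other split also mixes DMSO and DSF libraries in each group, which adds the group difference to the spread. Their 0 calls therefore say nothing about chance. An effect of DSF on transcript levels remains a hypothesis.

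The effector and interferon lists were lower, with medians of -0.45 and -0.31, by camera with the preset correlation and not with an estimated one (adjusted p = 0.0615 and 0.0933). A lower share of T cells would lower lineage genes as much, but the lowest of 7, Cd8a, was at -0.23 and their median at -0.08. A loss of B, myeloid and dendritic cells together is likewise unlikely as the whole cause, since the lower quartile of their 29 markers was -0.19 and their median 0.01. These pooled markers cannot decide on a loss of dendritic cells alone, which stays open. Xcr1 fell to 0.506 and Clec10a, at 0.842 CPM in DMSO, to 0.368 of its DMSO level, while 11 of 14 myeloid and dendritic markers did not pass. Flt3, Clec9a and Siglech reached at most 9, 1 and 0 counts in any library, DMSO included, too few to be tested. Those markers thus gave no sign of a sizeable share of dendritic cells in DMSO that could be lost. For lists, 1 of the 10 splits gave as many shifted, the real one with 6 against 2 in the highest other, again too few for a share under 0.05. The other splits again mix both groups, so they cannot decide on chance. A hypothesis that genes of both the interferon-beta and the interferon-gamma response fell stayed open. The beta term passed camera with the preset correlation and not with an estimated one (adjusted p = 2.12e-08 and 0.635). With the preset correlation, response to interferon-gamma had a camera adjusted p of 0.0825 and cellular response to interferon-gamma one of 0.468. Of the 65 genes of the cellular response to interferon-gamma, 18 were lower and 8 higher, with a median of 0.01.

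Ciliary genes stood among the largest rises, Tub among them. The hypothesis that genes annotated to the cilium rose together met its prediction with the preset correlation (camera's adjusted p = 0.000122, 58 of 193 higher and 6 lower) and not with an estimated one (adjusted p = 0.635). It was drawn from rises seen in these same libraries, and the term holds some of those genes. The test therefore describes the pattern and gives no separate support for it. A trend of gene length and GC content is unlikely as the whole cause, since adjusted p = 0.00016 with it taken out. Reads of overlapping genes are unlikely too, since adjusted p = 0.000186 among the 126 cilium genes with no overlapping gene. An effect of DSF on these genes stays a hypothesis.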
